A study of Mus musculus with 9 samples.

How the data were processed

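RNA was measured in 3 tissues of the hindlimb of CD-1 mouse embryos at embryonic day 16: the meniscus, the articular cartilage and the cruciate ligaments of the knee. Each tissue had 3 arrays, 9 in all. Per the labels' protocols, RNA was extracted and treated with DNase using the Arcturus PicoPure kit, amplified with the Ovation Pico whole-transcriptome system of NuGEN, labelled with biotin using the Encore BiotinIL module, and hybridised to Illumina bead arrays. Nothing in the labels says that the replicates of a tissue came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

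The deposited scanner tables hold, for each probe and array, a signal intensity on a linear scale and a detection p-value; GenomeStudio is named in the submitters' processing notes, with its version not given in the sources used here. The meniscus and cartilage arrays form a set of 6 arrays and the ligament arrays a set of 3. A value table of the authors' processed intensity per probe was deposited beside the scanner output. Its medians were between 99.9 and 100.0 on the meniscus and cartilage arrays and between 172.2 and 172.3 on the ligament arrays, and the values sorted within an array were nearly identical within each set, so the sets had been normalized separately. These values were used only as an alternative for meniscus against cartilage. The method behind them is not given in the sources used here, and their scale is linear.

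The rows of the scanner tables carry no gene names. Each of the 45281 scanner rows was therefore matched to a row of the authors' value table by its ranks on the 9 arrays, and the value table's probe names were paired with gene symbols through the platform annotation. Every row found 1 partner. The median largest rank difference to the partner was 96 places, against 4549.5 places to the second nearest row, and leaving out any 1 array from the matching gave the same partner for 100% of rows. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, with 19057 distinct symbols. The gene identifiers of 34807 probes were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only, and 0 symbols needed updating. Probes with several symbols or none were not given a gene name.

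Signals were background-corrected with limma's neqc function, with the negative controls' mean and spread inferred from the detection p-values and an offset of 16, then quantile normalized over the 9 arrays and put on the log2 scale. A probe was kept if its detection p was below 0.01 on all 3 arrays of at least 1 tissue, which left 12538 of 45281 probes. For each gene the kept probe with the highest mean was used, which gave 9166 features: 7234 named genes and 1932 probes without a symbol. A gene counted as not above background in a tissue when none of its probes had a detection p below 0.01 on any of the 3 arrays. In that case, or where the probe used was not above background there and another was, the difference is given as a bound: the bright tissue's mean normalized log2 value against the dim tissue's mean of, for each array, the higher of the lowest signal among detected probes and the probe's own value. No fold is given where that bound was under 1 or where both tissues were below background. The precision of every value is limited by the number of arrays.

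Group means were fitted with limma (lmFit and eBayes) over all 9 arrays, with 1 shared estimate of the spread, and the 3 contrasts between tissues were taken from that fit. P-values were adjusted by Benjamini and Hochberg's method over the 9166 features within each contrast, and a gene was called at an adjusted p under 0.05. All counts are of named genes unless stated otherwise. A moderated F test over the 3 tissues gave the number of genes differing among them. The meniscus signature was the set of genes called in the same direction against both other tissues. The position of the meniscus was computed per gene as (meniscus minus cartilage)/(ligament minus cartilage) on the log2 scale, over genes called between ligament and cartilage, as a median over genes for each meniscus array. Overlaps between contrasts that share arrays were set beside 50 simulations of unchanged groups, with the same spread in every tissue, and beside the overlap of independent lists.

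The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The 25 lists covered matrix, signalling and patterning genes and markers of other cell types. Those with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 57 tests, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes; fry's directional p asks whether the list's genes move, on balance, one way, and its mixed p whether they change in either direction, and neither compares the list with other genes. The named genes were 8 landmark genes whatever their values; for each contrast, the 10 largest rises and 10 largest falls among called genes whose arrays did not overlap between the tissues and which were detected on all 3 arrays of the higher tissue; the signature genes; and up to 4 called members of each list with the largest differences, or its 2 brightest members where none was called. Symbols that are only clone names were passed over.

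Alternatives covered the background correction, the normalization, the detection filter, the choice of probe, the variance model, array weights, the replicate number as a block, the threshold and leaving out each array in turn. Of those added after seeing the data, 1 used the 6 meniscus and cartilage arrays alone, 1 used named genes only and 1 gave each tissue its own weight. Procedures were tested on simulated data of 9166 features, 100 changed by 2-fold and 100 by 4-fold. For meniscus against cartilage, the 9-array fit recovered 44% of 2-fold and 72% of 4-fold changes with 1 false call, and the 6-array fit recovered 56% and 91% with 10 false calls. For ligament against cartilage, the 9-array fit recovered 27% of 2-fold and 76% of 4-fold changes with 17 false calls. In the list tests, the raised list was called in 2 of 2 tests and the other lists in 0 of 54. The simulated genes varied independently of each other. In the data the estimated correlation between a list's genes ran from -0.03 (cell cycle) to 0.61 (macrophage and osteoclast). The 0 of 54 therefore does not show how many false list calls correlated genes would give. A position set at 0.5 was recovered as 0.485, for genes changed by 4-fold in ligament only, so smaller changes were not covered. Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.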

Results

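Gene expression was profiled in 3 tissues that lie side by side in the knee of CD-1 mouse embryos at embryonic day 16. The meniscus is the fibrous cartilage pad between femur and tibia, the articular cartilage is the hyaline layer covering the bone ends, and the cruciate ligaments are the dense bands that tie both bones together. Each tissue was measured on 3 Illumina arrays of 45281 probes. Scanner signals had medians between 93.4 and 101.2 on the meniscus arrays, between 99.5 and 103.8 on the cartilage arrays and between 147.4 and 209.7 on the ligament arrays. Probes with a detection p below 0.01 made up 28.9% to 31.9% of all probes on the meniscus arrays, 29.4% to 35.6% on the cartilage arrays and 18.0% to 20.9% on the ligament arrays. Of the 9166 features tested, 8202 were detected on all 3 meniscus arrays, 8310 on all 3 cartilage arrays and 4524 on all 3 ligament arrays.

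The landmark genes of skeletal tissue separated the 3 tissues in part. Sox9, the transcription factor that directs cartilage formation, had a mean normalized log2 level of 12.14 ± 0.05 (SD, n = 3) in cartilage, 11.50 ± 0.28 in meniscus and 10.52 ± 0.24 in ligament. Col2a1, the main collagen of hyaline cartilage, stood at 11.22 ± 0.04 in cartilage, 10.22 ± 0.37 in meniscus and 10.70 ± 0.26 in ligament. Acan, the large aggregating proteoglycan of cartilage, stood at 9.42 ± 0.37, 7.73 ± 0.33 and 7.004 ± 0.64 in the same order. Col1a1, the main collagen of tendon, ligament and bone, was brightest in ligament at 10.59 ± 0.11, against 9.48 ± 0.17 in meniscus and 9.18 ± 0.20 in cartilage. Gdf5, a signal of the forming joint, stood at 6.97 ± 0.60 in meniscus and 6.59 ± 0.85 in cartilage and was not above background on any ligament array. Of the 8 landmark genes 5 could be tested. The tendon genes Scx and Tnmd did not pass the detection filter, with Scx detected on 1 ligament array and Tnmd on 0 arrays, and no probe was named Prg4.

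Arrays of a tissue resembled each other most in meniscus and cartilage. The median Pearson correlation across genes was 0.950 between meniscus arrays, 0.941 between cartilage arrays and 0.920 between a meniscus and a cartilage array, and it was 0.851 between ligament arrays. Ligament arrays correlated hardly less with meniscus arrays (0.844) and with cartilage arrays (0.831) than with each other. The median within-tissue SD of named genes was 0.25 in meniscus, 0.26 in cartilage and 0.50 in ligament. The moderated F test of limma called 1060 named genes as differing among the 3 tissues. Without 1 of the meniscus arrays that count was 645, 529 or 557 (replicates 1 to 3), and without 1 of the cartilage arrays it was 682, 535 or 588.

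Meniscus was compared with articular cartilage to find what sets the fibrous pad apart from the hyaline tissue beside it. Among the genes that rose most in meniscus were 3 genes of secreted signalling proteins and a matrix enzyme. Rspo2, a secreted enhancer of Wnt signalling, rose by 3.13 ± 0.46 (log2, SE; n = 3 arrays per tissue), which is 8.73-fold, and Lox, the enzyme that cross-links collagen and elastin, rose by 2.76 ± 0.45 (limma, Benjamini-Hochberg adjusted p = 0.0238 and 0.0314). In cartilage the probe of Rspo2 was above background on only 2 of 3 arrays. The growth factor Igf1 rose by 2.37 ± 0.37 and its binding protein Igfbp3 by 2.23 ± 0.27. Cartilage genes were lower in meniscus: Comp, a cartilage matrix glycoprotein, fell by 3.59 ± 0.63, and the forkhead factor Foxa3, not above background on any meniscus array, was at least 13.5-fold lower than in cartilage.

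In all, limma called 30 named genes as higher and 25 as lower in meniscus than in cartilage at a Benjamini-Hochberg adjusted p under 0.05. At an unadjusted p under 0.05 there were 825 genes, and the arrays of both tissues did not overlap for 1881 genes, 26.0% of those tested. Chance gives 10% for genes picked without regard to tissue. The detection filter looked at each tissue's arrays, so the share given by chance here may be higher and was not computed. The other genes among the 10 largest rises were Vat1l (2.66), the small leucine-rich proteoglycan Kera (2.60), the myosin light chain Myl9 (2.58), the lipoxygenase Alox12 (2.47), the matrix protein Spon2 (2.42) and Olfml1 (2.23). The other largest falls were the cytokine-like cartilage protein Cytl1 (-3.53), the Wnt inhibitor Wif1 (-3.05), Cnmd, which encodes chondromodulin (-2.91), Moxd1 (-2.76), the proteoglycan Prelp (-2.71), the kinase Stk26 (-2.60) and the collagen Col9a2 (-2.58). Snorc, a proteoglycan of chondrocytes, was not above background on any meniscus array and was at least 5.41-fold lower than in cartilage. Adjusted p for these 20 genes lay between 0.0061 and 0.0445. In the lower tissue, the probe used was above background on only 1 of 3 arrays for Kera, Myl9, Alox12 and others. For Spon2, Olfml1, Cytl1 and Moxd1 it was above background on 2.

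The plot of the 10 largest rises and 10 largest falls shows these genes array by array.

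**Figure D1:**
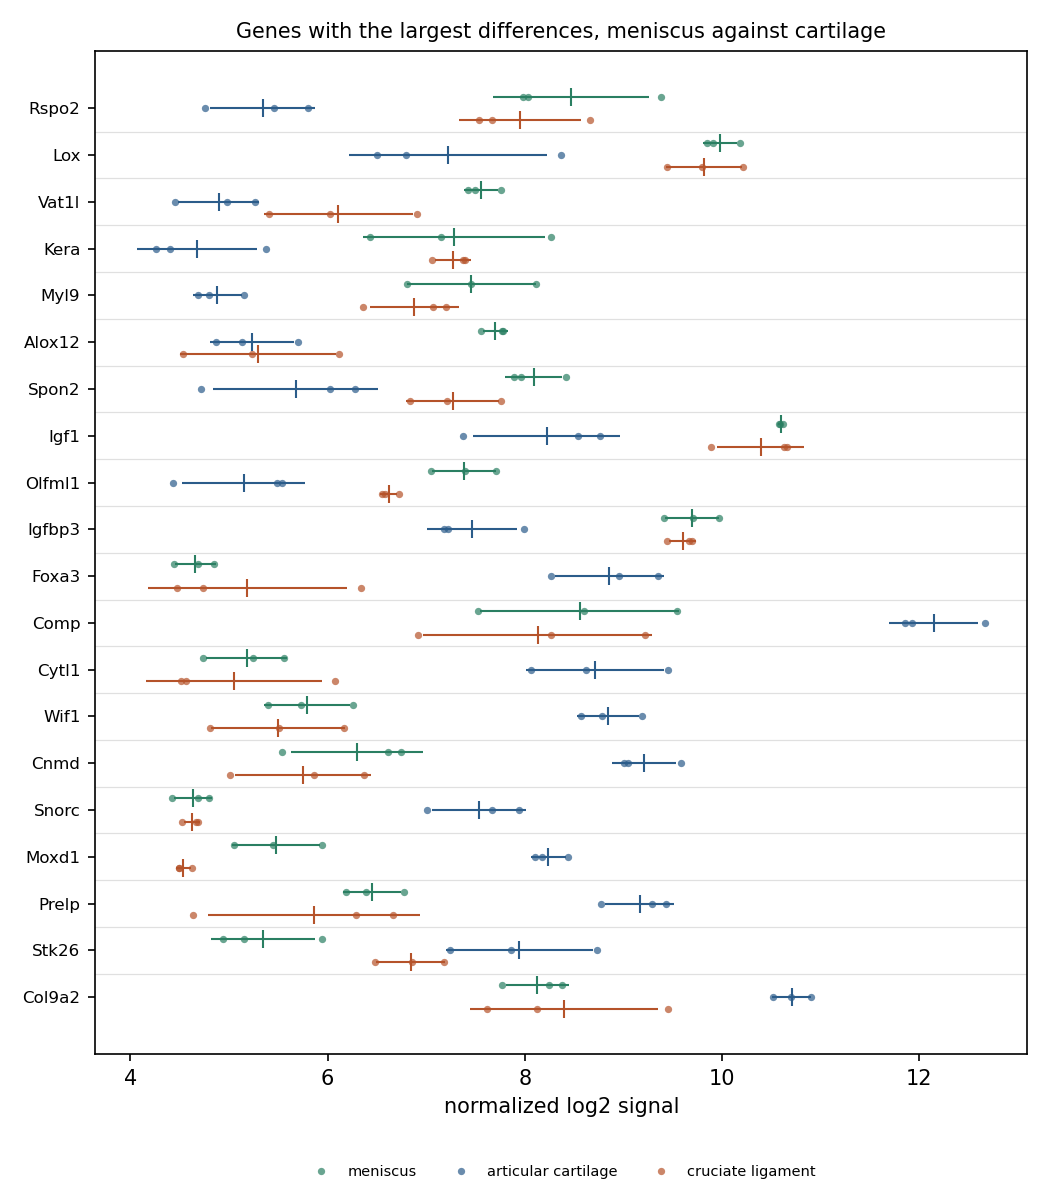
Normalized log2 signal of the 10 named genes with the largest rise and the 10 with the largest fall in meniscus relative to articular cartilage, on the 3 arrays of each tissue (dots are arrays, ticks are means and bars are the SD). Igf1 lay at 10.59 in meniscus and 8.22 in cartilage, and Comp at 8.56 and 12.15.

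Of the 21 tested genes of cartilage matrix, 0 rose and 7 fell in meniscus over all genes, and 19 fell when adjusted over the list alone. With the 6 meniscus and cartilage arrays alone, 18 fell over all genes. Comp, Cytl1, Cnmd and Snorc led the list, whose mean was -2.33 (camera, Benjamini-Hochberg adjusted p = 1.15e-27; adjusted p = 0.161 with an estimated correlation). Among 10 chondrocyte regulators, Foxa3 fell over all genes and 5 fell when adjusted over the list alone, with a list mean of -0.88 (camera, adjusted p = 0.00017; adjusted p = 0.161 with an estimated correlation). Of the landmarks, the differences were -1.004 for Col2a1 (limma adjusted p = 0.116), -1.68 for Acan (0.0731), -0.64 for Sox9 (0.306), 0.30 for Col1a1 (0.671) and 0.38 for Gdf5 (0.832), and none passed the test. The 3 probes of Col2a1 differed by -2.46, -1.004 and -0.66. With the 6 meniscus and cartilage arrays alone, Acan passed at an adjusted p of 0.0181 (0.00281 to 0.308 over all its alternatives) and Col2a1, then read from another probe, at 0.0195 with a difference of -2.31 (0.0158 to 0.423).

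Genes of hypoxia response and glycolysis lay lower in meniscus as a group, with a mean of -0.50. By limma 0 of the 26 members were called over all genes, 8 were lower at an unadjusted p under 0.05, and 4 fell when adjusted over the list alone (camera, adjusted p = 2.05e-06; adjusted p = 0.161 with an estimated correlation).

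Lists of fibrous matrix had positive means with members in both directions. Of 16 tendon and ligament markers, Kera rose and the proteoglycan Fmod fell by 1.33, and adjusted over the list alone 3 rose and 1 fell (mean 0.63; camera, adjusted p = 0.00108; adjusted p = 0.173 with an estimated correlation and 0.0793 for genes detected on all 9 arrays). Of 17 small leucine-rich proteoglycans and elastic fibre proteins, Aspn (1.93) and Mfap4 (1.30) rose and Prelp fell, and adjusted over the list alone 4 rose and 1 fell (mean 0.37; camera, adjusted p = 0.00383; adjusted p = 0.173 with an estimated correlation). Of 16 collagens of dense connective tissue, Col4a1, a basement membrane collagen, rose by 1.66, and adjusted over the list alone 1 rose and 1 fell (mean 0.26; camera, adjusted p = 0.013; adjusted p = 0.173 with an estimated correlation). That call was lost with the 6 arrays alone (adjusted p = 0.0522) and with only both tissues in the fit (0.0766), in a range over all alternatives from 0.000167 to 0.173. Of 21 genes of matrix cross-linking and remodelling, Lox rose, and adjusted over the list alone 4 rose and 1 fell (mean 0.41; camera, adjusted p = 0.0347; adjusted p = 0.216 with an estimated correlation). That call was lost without meniscus replicate 2 (adjusted p = 0.127), cartilage replicate 1 (0.0726) or ligament replicate 2 (0.0846), in a range over all alternatives from 0.000708 to 0.216.

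Camera at the preset correlation called 3 marker lists of other cell types as higher in meniscus than in cartilage. The 10 macrophage and osteoclast genes had a mean level of 6.43, 7.78 and 7.42 on the meniscus arrays and 5.10, 5.12 and 5.40 on the cartilage arrays. Their mean difference was 2.01, with 0 members called by limma over all genes, 9 higher at an unadjusted p under 0.05 and 9 higher when adjusted over the list alone (camera, adjusted p = 9.66e-09; adjusted p = 0.216 with an estimated correlation). The 12 endothelial genes averaged 5.85, 6.71 and 6.37 on the meniscus arrays and 5.26, 5.35 and 5.37 on the cartilage arrays. Their mean difference was 0.98, with 0 members called by limma over all genes, 7 higher at an unadjusted p under 0.05 and 5 higher when adjusted over the list alone (camera, adjusted p = 8.43e-05; adjusted p = 0.253 with an estimated correlation). Of 10 smooth muscle and pericyte genes, Myl9 rose and Cspg4 fell by 1.89, and adjusted over the list alone 3 rose and 1 fell (mean 0.74; camera, adjusted p = 0.00299; adjusted p = 0.173 with an estimated correlation and 0.105 for genes detected on all 9 arrays). Haemoglobin Hba-a1, from blood, stood at 8.57 ± 0.31 in meniscus and 7.84 ± 0.63 in cartilage (limma adjusted p = 0.435). Of 4 erythroid genes limma called 0 over all genes, 3 were higher at an unadjusted p under 0.05 and 1 when adjusted over the list alone. They averaged 7.40, 7.41 and 7.85 on the meniscus arrays and 6.43, 7.03 and 6.33 on the cartilage arrays. With the 6 meniscus and cartilage arrays alone, limma called 6 macrophage, 4 endothelial and 0 erythroid genes as higher.

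Camera called no signalling list as a group in the main fit, though single members were called. Among 11 Wnt genes, Rspo2 rose and the secreted inhibitors Wif1 and Frzb (-2.11) fell (camera, adjusted p = 0.154; 0.0399 with the authors' values, 0.0434 by fry, and 0.0399 to 0.41 over all its alternatives), with 1 rise and 3 falls when adjusted over the list alone. Among 16 FGF and IGF genes, Igf1 and Igfbp3 rose (camera, adjusted p = 0.238; 0.0306 by fry, and 0.0306 to 0.448 over all its alternatives), with 3 rises and 3 falls when adjusted over the list alone. Among 24 TGF-beta and BMP genes, the inhibitory helix-loop-helix factor Id4 fell, also when adjusted over the list alone (camera, adjusted p = 0.582). Its probe used here was not above background on any meniscus array, where Id4 was at least 3.20-fold lower. Gli1, a hedgehog target in the growth plate list, fell by 2.07, and 3 of the 4 tested members fell when adjusted over the list alone.

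With the 6 meniscus and cartilage arrays alone, limma called 142 genes as higher and 115 as lower, including all 55 genes above in the same direction, and it called 65 and 48 without ligament replicate 1 and 71 and 58 without ligament replicate 3. It called 6 and 6 without cartilage replicate 3, 1 and 3 without meniscus replicate 1, 0 and 3 without meniscus replicate 3, and 0 and 0 without meniscus replicate 2, cartilage replicate 1 or cartilage replicate 2, where 316 and 266, 291 and 268, and 360 and 281 genes had an unadjusted p under 0.05 (357 and 337 without meniscus replicate 3); each of the 37 named calls was lost without at least 3 of the 9 arrays in turn.

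Meniscus was compared with the cruciate ligament, the dense fibrous neighbour of the same joint. The median named gene differed by 0.27 (log2) between meniscus and ligament and by -0.23 between ligament and cartilage, against 0.06 and -0.04 under cyclic loess normalization. It also depended on the detection filter, with 0.08 and -0.02 for genes detected on all 9 arrays and -0.02 and 0.03 without a filter. Differences that involve ligament are given relative to the median gene of their contrast in the main fit, while the tests were run on the differences themselves. The short-chain collagen Col8a1, not above background on any ligament array, was at least 9.35-fold higher in meniscus. The IGF binding protein Igfbp2 rose by 3.02, thrombomodulin, encoded by Thbd, by 2.85 and the basement-membrane-zone collagen Col15a1 by 2.77 (limma, Benjamini-Hochberg adjusted p = 0.00203, 0.00351 and 0.00794). In the other direction, the antiviral zinc finger gene Zc3hav1 was not above background on any meniscus array and was at least 12.3-fold lower there, and the microtubule-associated ubiquitin ligase gene Mid1 fell by 3.70.

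Limma called 674 named genes as higher and 190 as lower in meniscus than in ligament at a Benjamini-Hochberg adjusted p under 0.05. The fit used 1 shared spread, although the median within-tissue SD was 0.50 in ligament and 0.25 in meniscus. Adjusted p may therefore be too low in contrasts with ligament. At an unadjusted p under 0.05 there were 2119 genes. The arrays of both tissues did not overlap for 31.6% of genes, where chance gives 10% only without the tissue-based detection filter. The other largest rises were the splicing-factor-like gene Ralyl (at least 3.30-fold), the zinc finger gene Snai3 (2.62), the scaffold gene Slc9a3r1 (2.52), Cntnap4 (at least 1.99-fold), the EGF-family ligand Hbegf (2.35) and the landmark Gdf5 (at least 1.76-fold). The other largest falls were the procollagen peptidase enhancer Pcolce2 (-2.77), the actin-binding caldesmon gene Cald1 (-2.69), Cst11 (-2.65), Jrk (at least 4.92-fold lower), the paired-box factor Pax9 (-2.62), Stxbp5l (-2.53), the adhesion gene Cadm1 (-2.52) and Pea15a (-2.49). Adjusted p for the 20 genes lay between 0.000209 and 0.0429. Before the median gene was taken off, the second probe of Col8a1 differed by 0.74, that of Stxbp5l by -0.17 and the 3 other probes of Cald1 by -2.50 to 0.24. Over the 3 contrasts, 72 named calls had another tested probe, which went the opposite way for 10 of them and was itself called by limma in 0 of these 10. These were Cald1 and Sox5 in both ligament contrasts, Slc8a1, Id2, Fgfr2 and Ccn1 between meniscus and ligament, and Fmod and Pmp22 between ligament and cartilage. In the lower tissue the probe used was above background on only 1 or 2 of the 3 arrays for 13 of the 37 named calls between meniscus and cartilage, 25 of 76 between meniscus and ligament and 27 of 88 between ligament and cartilage.

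Of 10 chondrocyte regulators, Sox9 (0.72), Sox5 (1.20), Barx2 (1.91) and Dlx5 rose and Nfatc2 fell by 1.62 relative to ligament. Dlx5 was not above background on any ligament array and has no fold here. Adjusted over the list alone 4 rose and 2 fell (camera, adjusted p = 0.954). Of the 21 cartilage matrix genes limma called 0, over all genes or over the list alone, with 1 higher and 2 lower at an unadjusted p under 0.05 (camera, adjusted p = 0.526). Acan differed by 0.46 and Col2a1 by -0.75 (limma adjusted p = 0.202 and 0.22), and the second probe of Acan differed by -0.62 before the median gene was taken off. Of 16 collagens of dense connective tissue, 4 rose, among them Col8a1, Col15a1 and Col6a1 (1.05), and Col1a1 fell by 1.38, and adjusted over the list alone 5 rose and 1 fell (camera, adjusted p = 0.502). Of 16 tendon and ligament markers, 3 rose, among them the early-response factors Egr1 (1.64) and Egr2 (1.15), while the tendon transcription factor Mkx (-1.48) and Fmod (-2.45) fell, and adjusted over the list alone 5 rose and 2 fell (camera, adjusted p = 0.664). Elastin, encoded by Eln, rose by 1.59 and Mfap4 fell by 2.04 among 17 proteoglycans and elastic fibre proteins, of which 2 rose and 1 fell (camera, adjusted p = 0.636), and 2 rose and 2 fell when adjusted over the list alone. Of 21 cross-linking and remodelling genes, Loxl1 (1.502) and Timp1 (1.02) rose (camera, adjusted p = 0.954), and 5 rose and 1 fell when adjusted over the list alone.

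Of 16 FGF and IGF genes, 6 rose and 0 fell, led by Igfbp2, Spry2 (1.22), Igf1r (1.20) and Fgfr2 (1.15), and 7 rose when adjusted over the list alone (camera, adjusted p = 0.0697; 0.0428 without meniscus replicate 1, and 0.00262 to 0.34 over all its alternatives). Before the median gene was taken off, both other probes of Fgfr2 went the opposite way, by -0.23 and -0.01 (limma adjusted p = 0.666 and 0.991). Of 17 joint interzone genes, Gdf5, the hyaluronan receptor Cd44 (0.95) and the hyaluronan synthase Has2 (0.71) rose, and 4 rose when adjusted over the list alone (camera, adjusted p = 0.608). Of 10 smooth muscle and pericyte genes, Cald1, Cspg4 (-1.68) and Mcam (-1.26) fell (camera, adjusted p = 0.196), also when adjusted over the list alone. With only genes detected on all 9 arrays, the list was called as lower in meniscus (camera, adjusted p = 0.0496). Hba-a1 fell by 1.89 relative to ligament, where it stood at 10.20 ± 0.14 before the median gene was taken off. Macrophage markers averaged 7.67, 6.16 and 5.32 on the ligament arrays and endothelial markers 6.57, 6.26 and 5.46; neither list was called against meniscus (camera, adjusted p = 0.489 and 0.954). Without ligament replicate 1 the macrophage list was called as higher in meniscus (adjusted p = 0.0366, in a range of 0.0366 to 0.982 over all its alternatives). For 7 of the 19 tested lists the mean was positive and the sign of camera's test negative, among them the cartilage matrix, chondrocyte regulator and endothelial lists.

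The 3 ligament arrays form a set of their own, so set and tissue cannot be told apart in this contrast or in the next. Counts of higher and lower genes moved to 289 and 73 without meniscus replicate 1, 215 and 62 without replicate 2, 240 and 79 without replicate 3, 446 and 116 without cartilage replicate 2, 469 and 120 without cartilage replicate 3, 286 and 80 with 1 weight per tissue and 341 and 248 under cyclic loess. Of 76 named calls, 36 were called without each of the 9 arrays in turn.

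The cruciate ligament was compared with articular cartilage as the pair of end points between which the meniscus was then placed. Among the largest rises in ligament, the actin-binding Cald1 rose by 3.35, the elastic fibre protein gene Mfap4 by 3.30 and the pericyte gene Rgs5 by 3.06 relative to the median gene (limma, Benjamini-Hochberg adjusted p = 0.00262, 0.000325 and 0.00549). The cartilage genes fell, led by Comp (-3.78), Cytl1 (-3.43), Col9a1 (-3.42), Matn1 (-3.29) and Cnmd (-3.23). Matn1 and Col9a1 stood apart on ligament replicate 3, at 10.08 and 9.62, against 5.55 and 6.29 on replicate 1 and 7.45 and 5.66 on replicate 2. Before the median gene was taken off they differed by -3.53 and -3.65, and by -4.72 and -4.87 without that array. The call of Matn1 was lost without 8 of the 9 arrays in turn and that of Col9a1 without 4. Moxd1, not above background on any ligament array, was at least 4.31-fold lower in ligament. Sox9 fell by 1.39 and Acan by 2.18, Col1a1 rose by 1.65, and Gdf5 was at least 1.38-fold lower in ligament, while Col2a1 differed by -0.29 (limma adjusted p = 0.179). Before the median gene was taken off, the 3 probes of Col2a1 differed by -2.26, -0.52 and -0.08, and the second probe of Acan by -0.58.

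Limma called 278 named genes as higher and 820 as lower in ligament than in cartilage at a Benjamini-Hochberg adjusted p under 0.05. The shared spread of the fit again understates that of the ligament arrays, so the error among these calls may exceed the threshold. In the simulated data this contrast had 17 false calls. Beside them, 27 of 100 changes of 2-fold and 76 of 100 changes of 4-fold were recovered. At an unadjusted p under 0.05 there were 2288 genes. Arrays of both tissues did not overlap for 33.6% of genes, where chance gives 10% only without the tissue-based detection filter. The other largest rises were the carboxypeptidase Cpm (3.57), the kinase-anchoring gene Akap5 (3.47), the cytokine-signalling suppressor Socs2 (3.36), Pea15a (3.19), Zc3hav1 (3.18), Mid1 (2.97) and Tmem255a (2.96). The other largest falls were Foxa3 (-3.44), the galectin Lgals3 (-3.39), Scrg1 (-3.36) and the gluconeogenic enzyme gene Fbp2 (-3.26). Adjusted p for the 20 genes with the largest rises and falls lay between 0.000325 and 0.0463.

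Of 21 cartilage matrix genes, 17 fell in ligament and 19 when adjusted over the list alone, with a list mean of -2.19 relative to the median gene (camera, adjusted p = 1.53e-09; adjusted p = 0.216 with an estimated correlation). Of 10 chondrocyte regulators, 5 fell, among them Sox9, Sox5 (-2.09) and Dlx5 (at least 1.91-fold), and Nfatc2 rose; adjusted over the list alone 1 rose and 6 fell (camera, adjusted p = 0.0539). That list had an adjusted p of 0.0302 without cartilage replicate 2 and 0.0479 without ligament replicate 1, in a range of 0.0011 to 0.256 over all its alternatives. Of 26 genes of hypoxia response and glycolysis, 8 fell, among them Higd1a (-1.85), the glucose transporter Slc2a1 (-1.54) and the angiogenic factor Vegfa (-1.10), and 14 fell when adjusted over the list alone (camera, adjusted p = 0.000775; adjusted p = 0.173 with an estimated correlation). Of 16 tendon and ligament markers, 5 rose, among them Kera (2.83), Thbs2 (2.74) and Mkx (1.99), and Egr1 fell by 1.90; 7 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0136; adjusted p = 0.216 with an estimated correlation). Without ligament replicate 3 that list had an adjusted p of 0.0648, in a range of 0.00606 to 0.216 over all its alternatives. Of 17 proteoglycans and elastic fibre proteins, 4 rose, among them Mfap4, Aspn (2.57) and Postn (1.14), and Prelp fell by 3.07; 4 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0339; adjusted p = 0.216 with an estimated correlation). That call was lost without cartilage replicate 2 (adjusted p = 0.087), without ligament replicate 3 (0.104) and under cyclic loess (0.0608), in a range of 0.00292 to 0.216.

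Collagens of dense connective tissue went both ways: Col1a1 and Col4a1 (2.09) rose, while 4 of the 16 fell, among them Col8a1 (at least 6.78-fold) and Col15a1 (-3.10), and adjusted over the list alone 3 rose and 5 fell. The second probe of Col8a1 differed by -0.60 before the median gene was taken off. The list's mean was -0.41 and its median 0.01 before the median gene was taken off, and camera's sign was positive (adjusted p = 0.643). Of 21 cross-linking and remodelling genes, 4 rose, among them Lox (2.83), Adamts4 (2.05) and Adamts1 (1.81), and 2 fell, among them P4ha2 (-1.67), with the same counts over the list alone (camera, adjusted p = 0.198). Rspo2 rose by 2.84 and Wif1 (-3.12) and Frzb (-1.64) fell among 11 Wnt genes, of which 1 rose and 4 fell (camera, adjusted p = 0.198), and 2 rose and 5 fell when adjusted over the list alone. Of 16 FGF and IGF genes, 3 rose, among them Igf1 (2.40) and Igfbp3 (2.37), and 5 fell, among them Fgfr2 (-2.38) and Igfbp2 (-2.22), with the same counts over the list alone (camera, adjusted p = 0.489). Of 24 TGF-beta and BMP genes, 1 rose and 6 fell, among them Id2 (-1.71) and Id4 (at least 1.57-fold lower), and 4 rose and 8 fell when adjusted over the list alone (camera, adjusted p = 0.954).

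Of 10 smooth muscle and pericyte genes, Cald1, Rgs5, Myl9 (2.23) and Mcam (1.79) rose, also when adjusted over the list alone (camera, adjusted p = 0.00191; adjusted p = 0.173 with an estimated correlation and 0.0591 without a detection filter). Of 12 endothelial genes, Aplnr (2.61) and Emcn (2.05) rose, also when adjusted over the list alone (camera, adjusted p = 0.00357; adjusted p = 0.41 with an estimated correlation). Without ligament replicate 1 the endothelial list had an adjusted p of 0.0594, in a range of 9.65e-05 to 0.41 over all its alternatives. Of 10 macrophage genes, Tyrobp rose by 2.47, also when adjusted over the list alone (camera, adjusted p = 0.00109; adjusted p = 0.414 with an estimated correlation and 0.15 by fry). The haemoglobin genes Hba-a1 (2.59) and Hbb-b2 (1.25) rose among 4 erythroid genes, of which 3 rose when adjusted over the list alone.

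Counts of genes higher and lower in ligament moved to 148 and 454 without cartilage replicate 1, 112 and 307 without replicate 2, 140 and 349 without replicate 3, 115 and 356 with 1 weight per tissue, and 404 and 481 under cyclic loess. Of 88 named calls, 54 were called without each of the 9 arrays in turn.

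The plot of gene lists shows the array-by-array means behind these group statements.

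**Figure D2:**
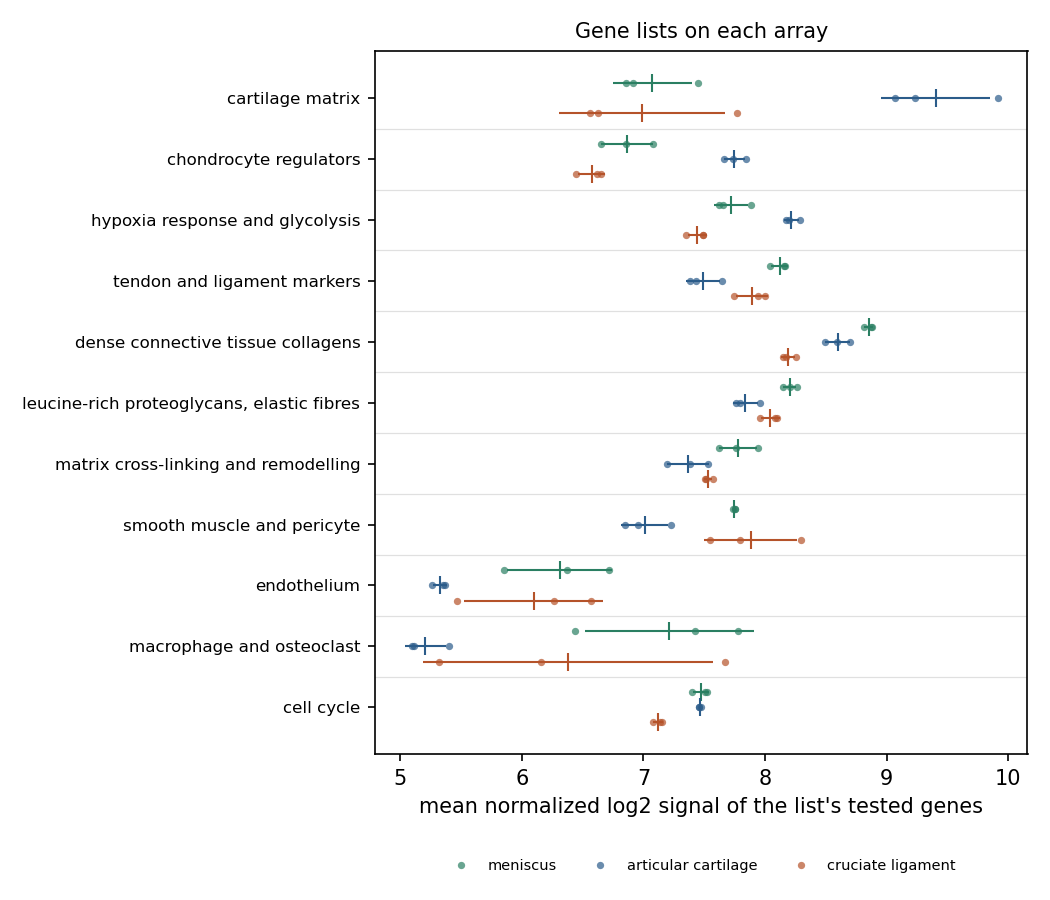
Mean normalized log2 signal of the tested members of 11 gene lists on the 3 arrays of each tissue (dots are arrays, ticks are means and bars are the SD). The cartilage matrix list averaged 9.41 in cartilage, 7.07 in meniscus and 6.99 in ligament, and the macrophage list spread from 5.32 to 7.67 over the ligament arrays.

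The series is named for a gene signature of the embryonic meniscus, taken here as the genes that differed from both neighbours in the same direction. There were 10 genes higher in meniscus than in both. The lipoxygenase gene Alox12 stood at 7.70 ± 0.13 (SD, n = 3) in meniscus, 5.24 ± 0.42 in cartilage and 5.29 ± 0.79 in ligament, and Ralyl at 7.88 ± 0.32, 5.73 ± 0.47 and 4.94 ± 0.57. Against cartilage and, relative to the median gene, against ligament, the others were Vat1l (2.66 and 1.18), Kcne1l, a gene of the potassium channel subunit family (2.11 and 1.04), Gatm, which encodes the first enzyme of creatine synthesis (2.05 and 1.05), the sodium-calcium exchanger Slc8a1 (1.69 and 0.73) and the forkhead factor Foxp1 (1.54 and 0.92). Fam13c rose by 1.78 against cartilage and was at least 1.27-fold higher than in ligament. In cartilage the probes of Alox12, Gatm and Fam13c were above background on only 1 of 3 arrays, and that of Kcne1l on 2. Calhm5 and the acetylcholine receptor subunit Chrna4 lay near the detection limit in meniscus, at 5.54 ± 0.19 and 5.51 ± 0.09, and were not above background elsewhere, at least 1.39-fold and 1.36-fold higher than in cartilage with no fold given against ligament.

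The 4 genes lower in meniscus than in both were Pcolce2, which enhances procollagen processing (-2.47 and -2.77), Stk26 (-2.60 and -1.76), the proteoglycan Cspg4 (-1.89 and -1.68) and the collagen-binding proteoglycan Fmod (-1.33 and -2.45). Of the 14 genes, 4 had other tested probes, and 0 of these 5 probes were called against both tissues. Before the median gene was taken off, the other probes of Slc8a1 differed by 0.30 and -0.23 from ligament (limma adjusted p = 0.795 and 0.648) and by 1.63 and 0.47 from cartilage (0.384 and 0.653). The other probe of Stk26 differed by -0.29 from ligament (0.728) and -1.94 from cartilage (0.119). Limma's Benjamini-Hochberg adjusted p for the 14 genes lay between 0.0196 and 0.0497 against cartilage and between 0.00203 and 0.0451 against ligament. Independent lists of the same lengths would share 2.80 higher and 0.66 lower genes. Part of the excess may come from the meniscus arrays that both contrasts use. Simulated unchanged groups with the same shared arrays shared 0 of either. They had a median of 0 calls in each contrast, so this 0 says little about the overlap. Across genes, the covariance of the log2 differences from cartilage and from ligament was 0.0854, against 0.0874 in those simulations, with correlations of 0.235 and 0.502. The simulations gave every tissue the same spread. In the data the median within-tissue SD was 0.25 in meniscus, 0.26 in cartilage and 0.50 in ligament. The simulated values therefore do not measure what the shared meniscus arrays give, and the near match of the covariances decides nothing. The counts were 25 higher and 10 lower genes without ligament replicate 1, 17 and 6 without ligament replicate 3, 1 and 0 without meniscus replicate 1, 0 and 1 without meniscus replicate 3, and 0 and 0 without meniscus replicate 2 or without cartilage replicate 1, 2 or 3. At an unadjusted p under 0.05 against both tissues, limma counted 173 higher and 78 lower genes over all arrays, 129 and 48 without meniscus replicate 1, 109 and 52 without replicate 2, 137 and 79 without replicate 3, and 116 and 56, 140 and 63, and 165 and 61 without cartilage replicates 1 to 3.

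**Figure D3:**
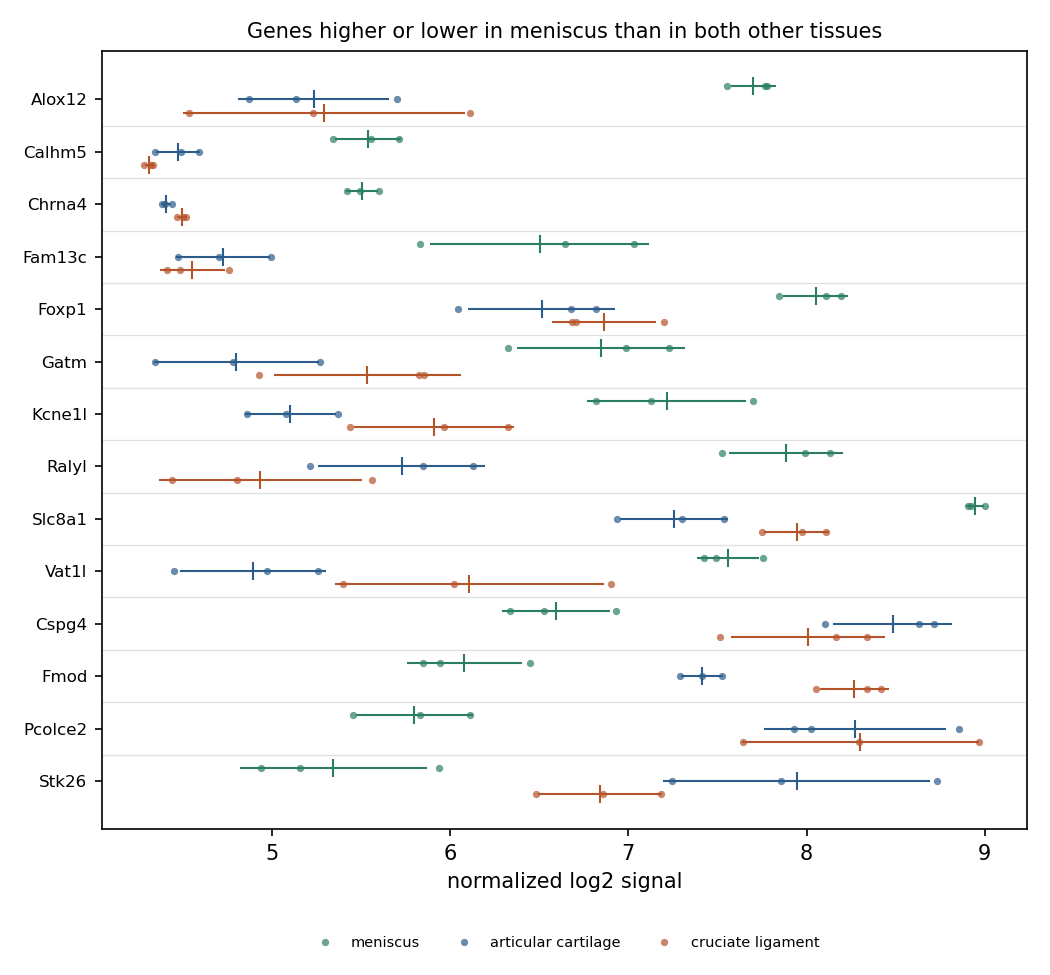
Normalized log2 signal of the 10 genes higher and the 4 genes lower in meniscus than in both articular cartilage and cruciate ligament, on the 3 arrays of each tissue (dots are arrays, ticks are means and bars are the SD). Alox12 lay at 7.70 in meniscus, 5.24 in cartilage and 5.29 in ligament.

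Where the meniscus lies between its neighbours was read from the 1098 genes called between ligament and cartilage, with cartilage at 0 and ligament at 1. The meniscus lay at 0.217 ± 0.021 (SD, n = 3 arrays), with 0.241, 0.206 and 0.205 on its arrays, and the slope over the same genes was 0.330. The SD covers the spread of the meniscus arrays only, and the median gene was not taken off here. Leaving out 1 array at a time placed the meniscus between 0.174 and 0.315. The cartilage mean enters both parts of the ratio, and the genes were chosen on the difference between ligament and cartilage. Noise in the cartilage arrays can therefore shift the position, by an amount that was not measured. Meniscus and cartilage arrays form a set without ligament arrays, so an effect of the set on the position cannot be told apart from the tissue. For 69.2% of these genes the meniscus mean lay between those of the other tissues, and for 24.6% it was closer to ligament. Genes higher in ligament placed it at 0.347 (278 genes) and genes lower in ligament at 0.176 (820 genes). Among the genes called in meniscus against cartilage, the set shared with ligament against cartilage was large. Of the 30 genes higher in meniscus, 19 were also higher in ligament, where independent lists would share 1.15, and of the 25 lower genes 20 were also lower, against 2.83. Rspo2, Lox, Igf1 and Igfbp3 were among the first and Comp, Cytl1, Wif1 and Cnmd among the second. Both contrasts use the same cartilage arrays, so part of the excess may come from them. Across genes, which are not independent replicates, the covariance of the log2 differences was 0.199, against 0.086 in simulated unchanged groups, while the correlations were 0.491 and 0.498. These simulations too gave every tissue the same spread, unlike the data. Their values therefore do not measure what the shared cartilage arrays give.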

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

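Among the alternatives, the tests on the 6 meniscus and cartilage arrays alone, on named genes only and with 1 weight per tissue were chosen after the results were seen. The main counts were 30 genes higher and 25 lower in meniscus than in cartilage, 674 and 190 against ligament, 278 higher and 820 lower in ligament than in cartilage, 1060 differing among the tissues, and a signature of 10 higher and 4 lower genes. The main position was 0.217. Direction was followed for the 209 values of the named genes and for the list tests, not for every called gene. No called value among them turned its direction under any of these alternatives. Apart from leaving out arrays, 3037 of 3530 values for named genes kept their side of the threshold, 477 calls were lost and 16 gained. For gene lists the numbers were 970 of 1052, 34 and 48. Estimating the correlation between genes ended all 17 of the 57 list tests that were called and gave each its highest adjusted p. Fry gained 17 list calls and lost 2, and without a detection filter 9 were gained and 4 lost. Testing all probes separately, named genes only, or requiring a 2-fold difference moved no count by over 1.5 times. The array number limits every value, and on the ligament arrays the lower share of probes above background limits the genes that can be compared.

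Against cartilage, limma called 142 higher and 115 lower genes on the 6 arrays alone, 93 and 86 with the authors' values, 60 and 56 without background correction, 55 and 53 with normexp on the signal alone, and 81 and 63 with trended and robust variances. It called 11 and 12 without a detection filter. Scaling to the 75th percentile gave 43 lower genes, the mean of all probes 39, and detection on all 9 arrays 49 higher genes. With only the compared tissues in the fit, the counts were 145 and 113 against cartilage, 282 and 81 for meniscus against ligament, and 118 and 373 for ligament against cartilage. With array weights they were 253 and 209, 376 and 97, and 157 and 516, and with 1 weight per tissue 196 and 158, 286 and 80, and 115 and 356. At an adjusted p under 0.01 they were 0 and 3 (825 genes at an unadjusted p under 0.05), 141 and 41, and 83 and 224, with 260 genes differing among the tissues, as a stricter threshold must lower them. Detection on all 9 arrays, which tests fewer genes, gave 626 genes differing among the tissues and a split of 311 higher and 198 lower for meniscus against ligament and 284 and 333 for ligament against cartilage. Cyclic loess gave splits of 341 and 248, and of 404 and 481. Except where the genes tested, the threshold or, against cartilage, a shared spread without the ligament arrays account for them, the cause was not tested.

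The signature had 18 higher genes with the 75th percentile, 24 higher and 15 lower with trended and robust variances, 29 and 17 with array weights, 20 and 13 with 1 weight per tissue, 6 and 2 with detection p under 0.05 on at least 3 arrays, 3 and 0 without a detection filter, and 0 and 0 at an adjusted p under 0.01. Limma counted 173 and 78 at an unadjusted p under 0.05 against both tissues. The lower genes numbered 10 without background correction, 9 with normexp, 14 with detection on all 9 arrays and 7 with only the compared tissues. The position was 0.254 with the 75th percentile, 0.312 with cyclic loess, 0.244 with the mean of all probes, 0.246 with only the compared tissues, 0.265 for genes at an adjusted p under 0.01 and 0.330 as a slope. The cause was not tested.

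With 1 array left out at a time, genes differing among the tissues numbered 529 to 1246. Higher and lower genes numbered 0 to 71 and 0 to 58 for meniscus against cartilage, 215 to 900 and 62 to 244 for meniscus against ligament, and 112 to 353 and 307 to 926 for ligament against cartilage. The signature had 0 to 25 higher and 0 to 10 lower genes. The position lay between 0.174 without ligament replicate 1 and 0.315 without cartilage replicate 3. Fewer arrays leave fewer degrees of freedom, but the counts above the main ones without ligament replicates 1 and 3 do not follow from that. For meniscus against cartilage, the ligament arrays enter the fit only through the shared spread. Without any of them in that fit, 145 higher and 113 lower genes were called. For the other counts the cause was not tested.

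With the replicate number as a block, 3 higher and 10 lower genes were called against cartilage, 636 genes differed among the tissues, and the signature had 2 higher and 0 lower genes. Residuals of arrays with the same number correlated at 0.02 to 0.15 between meniscus and cartilage and at -0.03 to 0.01 in pairs with ligament. Of the 9 arrays, 4 correlated best with their own number. These weak correlations do not show whether equal numbers share an embryo, litter or day, and nothing in the labels says so. Of the list tests, the call for proteoglycans and elastic fibre proteins in ligament against cartilage was lost with the block (adjusted p = 0.0533, in a range of 0.00292 to 0.216 over its alternatives), and the chondrocyte regulators were called (0.0398, 0.0011 to 0.256). It changed no other list call, and 55 of the 209 values for named genes lost their call. Slide as a block was not run, since the files used here give no slide, and the authors' values were tested only for meniscus against cartilage, since the sets of arrays had been normalized separately.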

Other observations

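The tests by signal strength, by cyclic loess, of the array set, of probe brightness, of the lowest and highest arrays and of the marker lists set against each other were chosen after the results were seen. The counts over other splits of the arrays were planned, except that splits with group names and splits with the ligament arrays kept in place were added after results of the first splits were seen. Several gene groups had no called member between meniscus and cartilage. By limma, 0 of 32 cell cycle genes (0 at an unadjusted p under 0.05), 0 of 28 cytosolic ribosomal protein genes (0), 0 of 18 limb patterning genes (1 higher and 2 lower), 0 of 18 immediate early genes (2 and 1), 0 of 17 joint interzone genes (2 and 0) and 0 of 6 adipocyte genes (2 and 0) were called. Camera's adjusted p for these lists was 0.954, 0.955, 0.537, 0.831, 0.238 and 0.526. Without cartilage replicate 3 the joint interzone list was called as higher in meniscus (adjusted p = 0.0377, in a range of 0.0377 to 0.641 over its alternatives).

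Against ligament, members of the same groups were called, with values relative to the median gene. Tbx18, a T-box transcription factor, rose by 1.60 in meniscus, as did the homeobox gene Hoxd10, which was not above background on any ligament array and has no fold, while Hoxa11, a patterning gene of the middle limb, fell by 2.40, among 18 limb patterning genes (camera, adjusted p = 0.683), with 4 rises and 1 fall when adjusted over the list alone. In ligament, Meox2 rose by 1.72 and Tbx18 and Shox2 fell by 1.46 and 1.29 relative to cartilage, with 2 rises and 4 falls over all genes and 2 and 5 over the list alone (camera, adjusted p = 0.954). Of 32 cell cycle genes, 6 rose and 1 fell in meniscus against ligament, among them the replication clamp Pcna (1.20) and the spindle gene Nusap1 (0.93), and 7 rose and 1 fell over the list alone (camera, adjusted p = 0.564). In ligament 1 rose and 6 fell against cartilage, over all genes and over the list alone, among them Pcna (-1.09) and the cyclin Ccna2 (-1.13) (camera, adjusted p = 0.502). The early-response genes Btg2 (1.11) and Ccn1 (0.64) rose in meniscus against ligament, with 2 rises and 1 fall over the list alone, and Btg2 (-1.19), Ccn1 (-0.96), Myc (-0.65) and Klf4 (-0.63) fell in ligament against cartilage, with 1 rise and 5 falls over the list alone (camera, adjusted p = 0.215 and 0.489). The ribosomal protein genes Rplp0 (2.07) and Rpl30 (1.24) rose in meniscus against ligament, also over the list alone, and 4 fell in ligament against cartilage, 5 over the list alone (camera, adjusted p = 0.0625 and 0.0646).

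The ribosomal list was called against meniscus without meniscus replicate 1 (adjusted p = 0.038) or ligament replicate 1 (0.0403), in a range of 2.14e-06 to 0.496 over its alternatives. It was called against cartilage without ligament replicate 1 (0.0403, 4.15e-06 to 0.496). In both contrasts, meniscus first, camera also called it without background correction (adjusted p = 0.00741 and 0.00872) and with normexp (0.0207 and 0.0246). The same held under cyclic loess (0.03 and 0.03), with each of the other detection filters and by fry. In meniscus against ligament the hypoxia and glycolysis genes Higd1a (1.44), Slc2a1 (0.58) and Hk1, which was not above background on any ligament array and has no fold, rose, also over the list alone (camera, adjusted p = 0.582), as did 3 TGF-beta and BMP genes, among them Id2 (1.23) and the receptor gene Acvr1 (1.22), 4 over the list alone (0.95). Of 11 Wnt genes limma called 0, with 3 higher at an unadjusted p under 0.05 (0.683). The adipocyte list had 0 calls in that contrast, with 3 higher at an unadjusted p under 0.05 (0.515), while Dlk1, a preadipocyte gene, fell by 1.05 in ligament against cartilage, where 2 fell over the list alone (0.954). Among joint interzone genes Gdf5 alone was called in ligament against cartilage, also over the list alone (0.954). Lists with under 5 tested genes had no group test. In meniscus against ligament, Fgfr1 (-1.31) fell in the growth plate list, Col22a1 (2.28), a collagen of tissue junctions listed with osteoblast genes, rose, and the sarcomere gene Ttn, whose probe used here was not above background on any meniscus array, was at least 3.28-fold lower relative to the median gene and 2.73-fold before it was taken off. In ligament against cartilage, the hedgehog receptor gene Ptch1 (-1.62), Col22a1 (-1.56) and the Schwann cell gene Pmp22 (-0.87) fell, Ttn rose by 1.61, and Gli1, not above background on any ligament array, was at least 2.75-fold lower. The epithelial gene Krtdap, also not above background there, was at least 1.46-fold higher in meniscus than in ligament.

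In other splits of the arrays, 1 of 100 drawn splits into 3 groups of 3, the tissues themselves, gave 1060 genes or more differing among the groups. The highest other split gave 398. The ligament arrays form a set of their own. A split that spreads them over several groups may give a low count for that reason alone. These splits therefore cannot decide whether that count reflects more than the ligament arrays standing apart. For each pair of tissues, 1 of the 10 splits of its 6 arrays, the real one, gave as many called genes, with 55, 864 and 1098 genes against a highest other of 0 each time, and 10 splits are too few for a share under 0.05. For the signature, 3 of 100 splits gave 10 or more higher genes and 2 of 100 gave 4 or more lower genes. Of these 100 splits, 96 spread the ligament arrays over several groups, and 95 of the 96 gave 0 higher and 0 lower genes by limma, so they say little about the signature. With the ligament arrays kept in place, 2 of 20 splits gave as many higher genes and 2 of 20 as many lower genes. The highest other, with 20 and 19 genes, is the real split with meniscus and cartilage exchanged, and 20 splits are too few for a share under 0.05. The highest others among the 100 splits, with 67 and 306 genes, put the 3 ligament arrays in the place of the meniscus, which points to the ligament arrays as a structure of the samples. For the 17 called list tests, 5 of 100 splits drawn with group names (highest other 23) and 4 of 100 drawn without them (highest other 20) gave as many, so chance cannot be excluded for that number.

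More genes were lower than higher in ligament, 78.0% of calls against meniscus and 74.7% against cartilage. Under cyclic loess the shares were 57.9% and 54.4%. Under 75th percentile scaling, which also does without quantile normalization, they were 81.1% and 82.4%. These alternatives went opposite ways. Quantile normalization of arrays with unlike signal distributions therefore stays undecided as an explanation. Among genes in the brighter part of the signal range the shares were 71.4% and 65.6%, against 83.5% and 83.0% in the dimmer part, and among genes detected on all 9 arrays, a filter that itself removes genes below background in ligament, they were 61.1% and 54.0%, which leaves the fewer probes above background on the ligament arrays undecided. The ligament set holds 0 arrays of meniscus or cartilage, so array set and tissue cannot be told apart for these genes. A difference between the tissues stays open and was not tested.

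Probes without a gene symbol made up 86 of the 190 features (45.3%) higher in ligament than in both other tissues, and 125 of the 575 features (21.7%) lower than in both. Features matched on mean signal would give 41.2 among the former, with an SD of 5.64 that treats features as independent. The observed number lies 7.94 of these SDs above, which argues against the brightness of unnamed probes. Features on the same arrays are not independent, and unnamed probes were not reduced to 1 per gene. The SD may therefore be too small, and it does not measure how likely chance is. Among the features lower than in both, the number lay 0.602 SD above. The array set cannot be told apart from the tissue here either, and a difference between tissues may also underlie the excess, which was not tested.

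The means of the macrophage and endothelial lists lay higher in meniscus than in cartilage, with 0 members called by limma over all genes in the main fit. Both camera calls were lost with an estimated correlation (adjusted p = 0.216 and 0.253). The lowest meniscus array exceeded the highest cartilage array by 1.03 in the mean log2 of the macrophage list and by 0.485 in the endothelial list, which argues against 1 array carrying the difference. The macrophage list rose by 1.02 more than the endothelial list (SD 0.218), but in cartilage both lists averaged only 0.137 and 0.260 above the detection floor of 5.07. Rises from so near the floor cannot be compared, so a lower share of chondrocytes raising every other cell type alike stays open. A difference between the tissues in these cells, or in what was dissected with them, may also underlie the pattern and was not tested.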
